A study of Mus musculus with 4 samples.

How the data were processed

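Total RNA from 4 cultures of p53-null mouse neural stem cells, NSC, NSC-Ceacam1L, NSCL61 and NSCL61-Ceacam1sh, was measured on 1 array each. Per the labels' protocols, vectors were transfected, cells were selected with hygromycin for 1 week, and Cy3-labelled RNA was made from 0.5 µg of total RNA. The labels do not state whether the cells of the NSC and NSCL61 arrays carried an empty vector. Groups were taken from the sample titles, and 1 array per group left no samples to average.

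Each deposited scanner file held 62976 spots of a single-colour Agilent mouse array (design 028005, coordinates on mm9), of which 59305 were not controls. Their intensity values (processed signal, background-subtracted and detrended within the array, with a modelled error per spot) were made by the authors with Agilent Feature Extraction 10.7.3.1 and protocol GE1_107_Sep09, per the file headers, whereas the submitters' processing notes name Agilent Feature Extraction 9.1. The deposited NSC file had been saved again with signals of at most 3 significant digits and 58 altered gene names, so names were taken from the other 3 files, whose spots were laid out identically. The deposited table of processed values is on a log2 scale. Over probes well above background, its differences between arrays had slopes of 1.0001, 0.9998 and 1.0000 and correlations across probes of 0.9997 to 1.0000 against the differences of the unscaled scanner signals, with offsets of -0.22 for NSC-Ceacam1L minus NSC, -0.27 for NSCL61-Ceacam1sh minus NSCL61 and 0.14 for NSCL61 minus NSC. Scale and direction were settled in this way, and the centring stayed unknown: the column medians were 0.25, -0.20, 0.00 and 0.03 for NSC, NSC-Ceacam1L, NSCL61 and NSCL61-Ceacam1sh, and only 10.7% of its probes had a median over the 4 arrays within 0.001 of 0. This table was used as an alternative only.

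Processed signals were divided by each array's 75th percentile over non-control spots and taken to log2. Outlier spots were left out (187, 143, 144 and 147 on the 4 arrays in the order above), no spot was saturated, and spots of a probe were averaged on the log2 scale. Of 55681 probes, 399 were printed 10 times and 33 were printed 2 times. A probe was called well above background by the scanner software's own test on at least 50.0% of its spots. Probes were named through the accessions in the files (27235) in the RefSeq gene table of GRCm38.p6, by symbol (3581) or older symbol (206), 111 kept the name of the file, and 24548 stayed without a gene name and out of the gene counts. Of several probes of a gene, the one with the highest mean over the 4 arrays was used, which concerned 6914 of 22252 genes. Among called genes with several probes well above background on both arrays, probes went in both directions for 20 of 339 (5.90%) between the NSC arrays, 167 of 1388 (12.0%) between the NSCL61 arrays and 47 of 677 (6.94%) between NSCL61 and NSC.

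The 75th percentiles of the signals were 480.0, 571, 439 and 541, and 27439, 29552, 29336 and 27421 probes were well above background. The median modelled error was 0.15 on the log2 scale on each array, and probes printed 10 times had a median SD of 0.0636, 0.0603, 0.0626 and 0.0562 between their spots. These values cover technical spread within an array only. The 8 spike-in probes well above background differed before scaling by a median of -0.14 between the NSC arrays (-0.40 to -0.06), -0.14 between the NSCL61 arrays (-0.25 to -0.11) and 0.09 between NSCL61 and NSC (0.05 to 0.17). Over 12444 genes well above background on all 4 arrays, the Pearson correlation of log2 signals across genes was 0.973 between NSC and NSC-Ceacam1L, 0.932 between NSC and NSCL61, 0.948 between NSC-Ceacam1L and NSCL61, and 0.860, 0.840 and 0.845 between NSCL61-Ceacam1sh and NSC, NSC-Ceacam1L and NSCL61.

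The 3 comparisons were NSC-Ceacam1L minus NSC, NSCL61-Ceacam1sh minus NSCL61 and NSCL61 minus NSC. A gene was evaluated when its probe was well above background on at least 1 of the 2 arrays. It was counted as higher or lower at a log2 difference of 1.0 or more in size. For such a count, the probe had to be well above background on the brighter of the 2 arrays. For genes seen on 1 array only, "at least" gives the bright array's value over the higher of the dim array's own value and the lowest signal among probes well above background there. The 31 gene lists (799 genes, of which 1 had no probe) covered pathways, cell types and checks. In list medians given with bounds, a gene seen on 1 array entered at its "at least" value, or at 0 where it had none. A gene had none, for instance, when another of its probes was well above background on the dim array. A list's median was set among those of 10000 random lists of the same size, matched in 20 bins of mean signal, as a description of these arrays, and lists with under 5 genes seen gave no median. The central 95% of these random lists is the random range. List medians lay above, inside and below it in 14, 9 and 6 of 29 lists between the NSC arrays, 9, 13 and 8 of 30 between the NSCL61 arrays, and 8, 12 and 9 of 29 between NSCL61 and NSC. The lists, the comparisons and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 10 largest positive and negative differences among genes well above background on both arrays with all their probes in 1 direction, up to 5 genes per direction with the largest bound, up to 8 members of each list that differed by 2-fold or more, largest first, up to 10 genes per direction pair of the overlap, and the sex-linked and housekeeping genes as checks. Some genes this rule takes are not reported here.

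The calculation was tested on simulated arrays built from each comparison's own signals. Only the modelled spot error was added as noise, so variation between arrays or cultures did not enter, and the rates below do not cover it. Changed genes were placed only among those well above background on both arrays. Genes changed by 3-fold or 6-fold were called in the right direction in 100% of cases in all 3 simulated comparisons (67 and 66 genes), and genes changed by 1.5-fold were called in 5.97% for NSC-Ceacam1L against NSC, 5.97% for NSCL61-Ceacam1sh against NSCL61 and 1.49% for NSCL61 against NSC. Unchanged genes were called in 0.037%, 0.008% and 0.038% of cases when well above background on both arrays, and in 11.7% of 1490, 13.3% of 2640 and 12.8% of 1887 when so on 1 array. Of 200 unchanged lists, 5.50%, 2.00% and 5.50% lay outside the random range, and lists shifted by 2-fold lay above it in 100% of 20.

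The alternatives were quantile normalization, median scaling, cyclic loess, normexp background correction with an offset of 50.0, 2 other filters on dim probes, the median of a gene's probes, leaving out saturated probes, the deposited value table, thresholds of 1.5-fold and 3-fold, and, chosen after seeing the data, scaling to the spike-in probes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for the normalizations.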

Results

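Gene expression was measured on 4 single-colour arrays of mouse neural stem cells, 1 array for each of 4 groups. All cells lacked p53 and were grown without serum. NSC were neural stem cells from the brain of E14.5 mouse embryos, and NSC-Ceacam1L were such cells carrying an expression vector for the long form of Ceacam1, an immunoglobulin-family adhesion molecule. NSCL61 was a p53-null line, known as a glioma-initiating line made from neural stem cells with an activated Ras, and NSCL61-Ceacam1sh were such cells carrying a short hairpin RNA against Ceacam1. Of 22252 genes with a probe, 14083 (63.3%) were well above background on the NSC array, 14947 (67.2%) on NSC-Ceacam1L, 14502 (65.2%) on NSCL61 and 13962 (62.7%) on NSCL61-Ceacam1sh. Each group had 1 array, so no difference below has a replicate check, no p-value is given, and the number of arrays limits the precision. The 4 arrays lay on 1 slide, 1 position per group, so position and group cannot be told apart. Differences are in log2 units of the scaled signal, a gene was counted as higher or lower from 2-fold, and an error after ± is that of the scanner software for the spots, which covers no biological variation.

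The manipulated gene itself could not be checked. None of the probes analysed here was named for Ceacam1, and 1 probe of its neighbour gene Ceacam2 (A_55_P2386236, chromosome 7, 26302671 to 26302730, minus strand, mm9) also listed a Ceacam1 transcript. Its signal was well above background only on the array labelled NSCL61-Ceacam1sh, at -4.34 against -5.00 on NSCL61, a difference of 0.66 ± 0.58 that was 1.12 under quantile normalization, 1.08 under median scaling, 1.01 under cyclic loess, 1.10 under spike-in scaling and -0.0016 with normexp background correction. The offset used with normexp draws differences of dim signals toward 0. Between NSC-Ceacam1L and NSC the probe differed by -0.06 ± 0.71, with both signals not well above background. Of 19 probes named for a Ceacam gene, 4 were well above background on any array. The groups are therefore named below as the arrays were labelled.

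The series set NSC-Ceacam1L against NSC to find genes that follow the gain of Ceacam1. Astrocyte genes were higher on the array labelled NSC-Ceacam1L, led by Gfap, the intermediate filament of astrocytes, which was 160.5-fold higher (7.33 ± 0.25; probe A_52_P52303, chromosome 11, 102751813 to 102751872, minus strand, mm9). Clu, a secreted chaperone made by astrocytes, was higher by 4.72 ± 0.20, the complement gene C4b by 5.38, and Socs3, the feedback inhibitor of STAT3 signalling, by 4.74 ± 0.20. The sphingosine-1-phosphate receptor S1pr3 (5.70), the nucleotidase Entpd2 (4.66) and Lgi4 (4.13) were also among the 10 genes with the largest positive difference of those well above background on both arrays. Among the same genes, the lactate exporter Slc16a3 had the largest negative difference (-5.70 ± 0.20), and hypoxia and glycolysis genes were lower, led by the hypoxia target Ankrd37 (-4.37) and the angiogenic factor Vegfa (-3.93 ± 0.20). Genes of DNA replication and mitosis were lower by smaller amounts.

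Of 26 astrocyte genes well above background, 15 were higher and 0 lower, with a list median of 1.28. Beside Gfap and Clu, these included the water channel Aqp4 (3.77), angiotensinogen Agt (3.07), the gap junction gene Gja1 (2.76) and the lipid carrier Apoe (2.39), and the gap junction gene Gjb6, seen on NSC-Ceacam1L only, was at least 19.2-fold higher. The STAT3 list held 9 higher and 4 lower genes of 27 (median 0.72, or 0.48 with genes seen on 1 array at their bound). The oncostatin M receptor Osmr was at least 27.2-fold higher and the protease inhibitor Serpina3n at least 5.23-fold higher, while Junb differed by 1.96 and Vegfa went the other way. In the BMP and TGF-beta list, 11 of 25 genes were higher and 1 lower (median 0.56), with Bmp4 at 3.28, the BMP target Id4 at 2.78, the matricellular gene Ccn1 at 3.33 and its relative Ccn2 at least 27.2-fold higher. The oligodendrocyte list (median 0.46, or 0.21 with bounds) held 8 higher and 1 lower genes of 23, among them the myelin gene Mbp (1.34).

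Interferon genes were higher on the array labelled NSC-Ceacam1L, with 19 of 29 list members higher, 1 lower and a median of 1.37 (1.20 with bounds). The GTPase Igtp differed by 2.49, Ifit3 by 2.36, Oasl2 by 2.25 and Usp18 by 2.18, whereas Mx1 was at least 6.56-fold lower. Of 19 genes of antigen presentation, 7 were higher and 0 lower (median 0.86, or 0.61 with bounds), including the immunoproteasome subunits Psmb8 (3.54) and Psmb9 (1.57) and the peptide transporter genes Tap1 (1.85) and Tap2 (1.95). The cadherin and adhesion list had 7 higher and 0 lower genes of 29 (median 0.46), with Pcdh8 at 2.58 and Cdh11 at 1.77. The fibroblast list (median 0.56; 4 higher and 1 lower of 14) held Thy1 (2.71) and Col6a1 (1.62).

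In the hypoxia and glycolysis list, 19 of 25 genes were lower and 0 higher, with a median of -1.68. Hexokinase Hk2 differed by -3.10, the pyruvate dehydrogenase kinase Pdk1 by -2.90, phosphofructokinase Pfkl by -2.67 and the mitophagy gene Bnip3 by -2.35. Of 29 genes of G1/S and replication, 18 were lower and 0 higher (median -1.04), including the origin-licensing genes Cdc6 (-1.61) and Mcm5 (-1.32). Of 31 mitotic genes, 12 were lower and 0 higher (median -0.98), including Aurkb (-1.70) and Cdk1 (-1.20). The Ras-MAPK list had a median of -0.38 with 1 higher and 4 lower genes of 29, among them the EGF-family ligand Areg (-1.44) and Ccnd1 (-1.13). Ribosomal protein genes had a median of -0.60, just below their random range of -0.54 to -0.30, with 0 of 43 past 2-fold. Cholesterol genes had one of -0.50, below a range of -0.42 to 0.02, with Stard4 (-1.42) alone lower.

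The remaining lists were also compared between the NSC-Ceacam1L and NSC arrays. Medians were 0.60 for chemokines and cytokines (1 higher and 2 lower of 11, with Ccl2 at -1.58 and Csf1 at 1.19, and a median of -0.43 without a filter on dim probes), 0.28 for EGFR, PDGF and FGF genes, 0.27 for neuron, 0.23 for Notch, 0.23 for extracellular matrix and 0.03 for unfolded protein response genes, all above the range of matched random lists. The medians of Src and focal adhesion (0.17), NF-kB (0.14), p53 target (0.13) and endothelial genes (0.06) lay inside it. So did those of neural stem (-0.01), Hedgehog (-0.01), microglia (-0.05), Wnt (-0.10) and housekeeping genes (-0.37), which all turned positive under cyclic loess and under spike-in scaling. In the neural stem list, 1 gene was higher (Id4) and 1 lower, the matrix gene Tnc (-2.46), and Hprt (-1.55) was the 1 housekeeping gene past 2-fold.

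In all, 1596 of 15260 genes (10.5%) were higher and 925 (6.06%) lower on the array labelled NSC-Ceacam1L than on NSC, and 307 differed by 10-fold or more with dim signals taken as measured. Of these calls, 709 higher and 298 lower genes were well above background on 1 array only, and with normexp background correction the counts were 741 and 523. The share of calls that were higher, 63.3%, was 76.3% under cyclic loess and 84.1% under spike-in scaling, the latter chosen after seeing the data, and 50.4% when genes were counted from 1.5-fold.

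**Figure D1:**
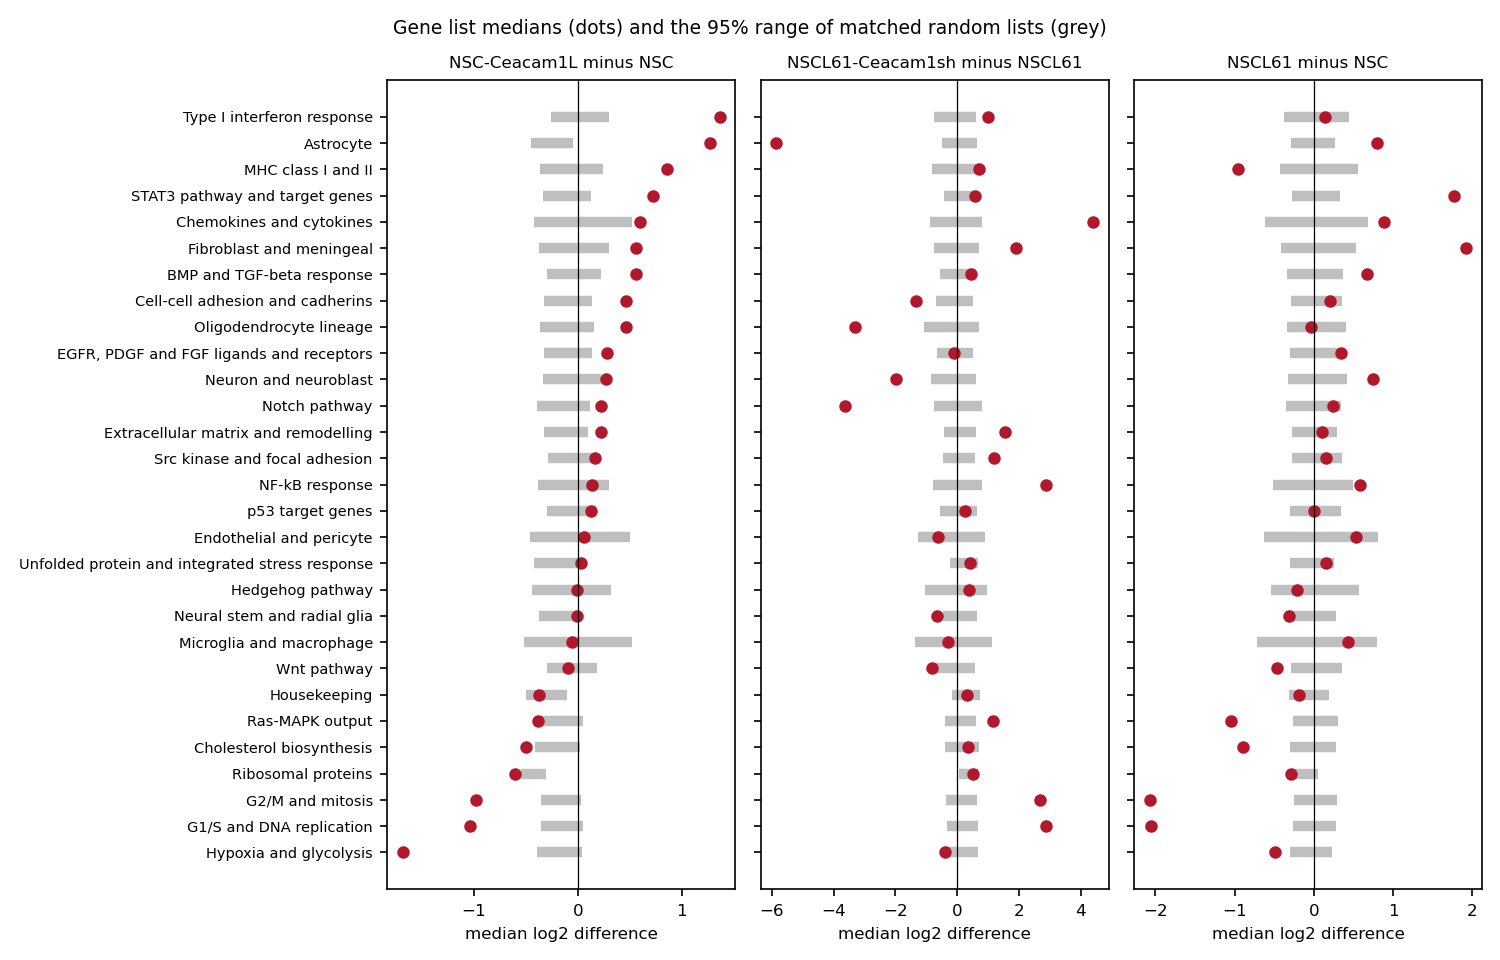
Median log2 difference of each gene list (dots, genes well above background on at least 1 of the 2 arrays) in the 3 comparisons, with the central 95% of 10000 random lists matched on signal in grey. Astrocyte genes had medians of 1.28, -5.85 and 0.80, and mitotic genes -0.98, 2.68 and -2.07; the hypoxia median of -0.40 between the NSCL61 arrays became 0.02 under median scaling and 0.04 under spike-in scaling.

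The series set NSCL61-Ceacam1sh against NSCL61 to find genes that follow the loss of Ceacam1 in the tumour line. Glial genes were far lower on the array labelled NSCL61-Ceacam1sh, led by the radial glial fatty acid binding protein Fabp7 (-12.37 ± 0.31), the astrocyte membrane protein Mlc1 (-12.14), Ttyh1 (-9.83), the brain proteoglycan Cspg5 (-9.76) and Apoe (-9.04 ± 0.21). Gfap was at least 6735-fold lower and Olig1, a transcription factor of oligodendrocyte precursors, at least 2634-fold lower, and neither was well above background on that array. Among genes well above background on both arrays, the largest positive differences included those of the calcium binding protein S100a6 (9.99 ± 0.21), Tm4sf1 (9.01), mesothelin Msln (8.32), the ephrin receptor Epha2 (7.92) and the urokinase receptor Plaur (7.88). The interleukin-33 receptor Il1rl1 was at least 3786-fold, the matrix metalloprotease Mmp3 at least 1691-fold and Cd34 at least 1671-fold higher. Replication and mitosis genes were higher as groups.

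Of 25 astrocyte genes, 21 were lower and 0 higher (median -5.85, or -5.52 with genes seen on 1 array at their bound), including the glutamate transporter Slc1a3 (-8.43) and Aldoc (-8.25). In the oligodendrocyte list, 16 of 23 genes were lower and 2 higher (median -3.33, or -2.44 with bounds). Olig2 was at least 419.6-fold, Sox8 at least 300.1-fold and Gpr17 at least 287-fold lower. The Notch list held 14 lower and 3 higher genes of 19 (median -3.63, or -2.41 with bounds), with the ligand Dll1 at -6.41, the receptor Notch3 at -6.68, the target Hey1 at -5.42 and the target Hes5 at least 1728-fold lower. Neuronal genes had 16 lower and 3 higher members of 25 with a median below the random range (-1.24 with bounds), including Tubb3 (-4.65). The neural stem list was mixed, with 12 lower and 6 higher genes of 28 and a median of -0.67: Lhx2 differed by -3.57, while Fut4 was at least 28.9-fold higher. Cadherin and adhesion genes (18 lower and 6 higher of 30, median -1.35) included Nrcam (-6.43), and Wnt genes (14 lower and 6 higher of 30, median -0.81, or -0.51, inside the random range, with bounds) included the feedback gene Axin2 (-3.56) and Fzd9 (-5.69).

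**Figure D2:**
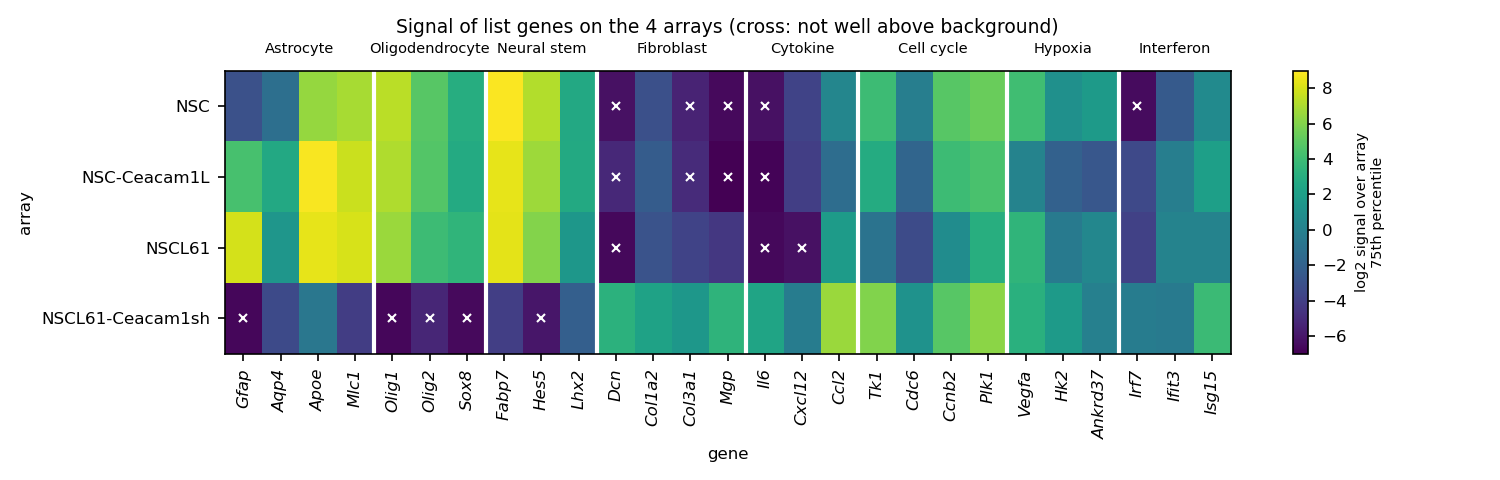
Log2 signal over each array's 75th percentile for genes of the fixed lists on the 4 arrays, to be read down each column, with crosses where a gene was not well above background. Olig1, Olig2, Sox8 and Hes5 carry a cross on the array labelled NSCL61-Ceacam1sh alone, and Dcn and Il6 carry one on the other 3 arrays.

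In the fibroblast list, 15 of 23 genes were higher and 6 lower on the array labelled NSCL61-Ceacam1sh (median 1.92). The collagens Col3a1 (5.25) and Col1a2 (5.14) and the matrix protein Mgp (7.83) were higher, the proteoglycan Dcn was at least 248-fold higher, and Col5a2 was at least 61.7-fold lower. The extracellular matrix list had 19 higher and 6 lower genes of 34 (median 1.53, or 1.19 with bounds), with the protease inhibitor Timp1 at 7.01 and osteopontin Spp1 at 6.45, whereas the brain proteoglycans Bcan and Ncan were at least 2883-fold and at least 531-fold lower. Of 16 chemokines and cytokines, 14 were higher and 1 lower (median 4.39, or 3.72 with bounds), including Ccl2 (4.82), Ccl5 (4.43) and Il11 (4.99), and Il6 was at least 126-fold higher. The NF-kB list (14 higher and 1 lower of 18, median 2.88, or 2.16 with bounds) included Bcl3 (5.20) and the prostaglandin synthase Ptgs2, at least 1403-fold higher. Of 27 interferon genes, 14 were higher and 5 lower (median 1.01, or 0.81 with bounds), among them Isg15 (3.75), Irf7 (3.61) and Cxcl10 (3.41), with Gbp2 at -3.19.

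Proliferation genes were higher on the array labelled NSCL61-Ceacam1sh. Of 28 genes of G1/S and replication, 26 were higher and 0 lower (median 2.87), including thymidine kinase Tk1 (6.89), Cdc6 (4.47) and E2f1 (4.09), and of 31 mitotic genes 29 were higher and 0 lower (median 2.68), including Birc5 (4.23), Ccnb2 (4.06) and Plk1 (3.22). The Ras-MAPK list held 16 higher and 2 lower genes of 32 (median 1.17), with the chromatin protein Hmga2 at 7.25, Fosl1 at 5.24, the phosphatase Dusp4 at 4.91 and the EGF-family ligand Ereg at least 518-fold higher. Of 30 Src and focal adhesion genes, 17 were higher and 2 lower (median 1.18), among them the integrin Itga3 (5.95), Zyx (2.42) and, in the other direction, the kinase Fyn (-2.92). The hypoxia list had 4 higher and 9 lower genes of 26, with Adm at -4.94 and Hk2 at 2.08, and its median of -0.40 became 0.02 under median scaling and 0.04 under spike-in scaling.

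The other list medians between the NSCL61 arrays lay inside the range of matched random lists. They were 0.59 for STAT3 (14 higher and 6 lower of 30), 0.71 for antigen presentation, 0.46 for BMP and TGF-beta, 0.41 for unfolded protein response, 0.37 for Hedgehog, 0.34 for cholesterol, -0.63 for endothelial and 0.52 for ribosomal protein genes. The median of p53 targets (0.25) turned negative under cyclic loess and quantile normalization, that of housekeeping genes (0.32) under cyclic loess, and those of microglia (-0.29) and of EGFR, PDGF and FGF genes (-0.10) turned positive under median and spike-in scaling. Within these lists, Bmp4 differed by 4.76, the insulin-like growth factor binding proteins Igfbp2 and Igfbp5 by -7.61 and -7.92, and the housekeeping genes Hprt, B2m and Tfrc by 3.30, 1.91 and 1.47. In the Ceacam and Psg list, 6 genes were seen, 3 higher and 1 lower (median 1.15, inside the range, or 0.52 with bounds). Psg23 differed by -1.50, and Psg19, Ceacam16 and Psg17, not well above background on NSCL61, were at least 6.19-fold, at least 1.69-fold and at least 1.66-fold higher. Xist, the RNA of the inactive X chromosome, was the only sex-linked list gene well above background, at 1.85, 1.26 and 0.42 on NSC, NSC-Ceacam1L and NSCL61 and at -4.05 on the array labelled NSCL61-Ceacam1sh (-4.47 ± 0.30 against NSCL61).

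In all, 3653 of 15552 genes (23.5%) were higher and 3763 (24.2%) lower on the array labelled NSCL61-Ceacam1sh than on NSCL61, and 1925 differed by 10-fold or more. The SD of the log2 differences over genes was 2.33, against 1.02 between the NSC arrays. Both these SDs and the 10-fold count take dim signals as measured. Over genes well above background on both arrays the SD was 1.60, against 0.69 between the NSC arrays. Of these calls, 954 higher and 1412 lower genes were well above background on 1 array only, and the share of calls that were higher, 49.3%, was 64.6% under median scaling and 65.0% under spike-in scaling.

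The series named as downstream of Ceacam1 the genes that differed in both Ceacam1 comparisons, and the overlap shows which did so in opposite directions. Here and below, "with Ceacam1L" and "with the hairpin" stand for the arrays labelled NSC-Ceacam1L and NSCL61-Ceacam1sh, each against its parental array. They do not credit a difference to the manipulation, which could not be checked. The complement gene C4b was higher with Ceacam1L (5.38) and lower with the hairpin (-7.11), as was Lgi4, a secreted glial protein (4.13 and -7.89). Gfap differed by 7.33 in the first comparison and was at least 6735-fold lower in the other, and the cytochrome gene Cyp4f14 differed by 4.30 and was at least 244-fold lower. Serpina3n was at least 5.23-fold higher and at least 17.0-fold lower. In the reverse direction, Snai2, a transcription factor of mesenchymal transition, was at least 1.96-fold lower with Ceacam1L and at least 177-fold higher with the hairpin, and the methyltransferase Nnmt was at least 2.26-fold lower and at least 26.3-fold higher. Among genes that moved alike, Ccn2 was at least 27.2-fold higher with Ceacam1L and differed by 4.82 with the hairpin. Thbs1 was at least 7.14-fold and at least 540.1-fold higher, Ptgs2 was at least 5.03-fold and at least 1403-fold higher, and Islr differed by -3.28 and -3.18.

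**Figure D3:**
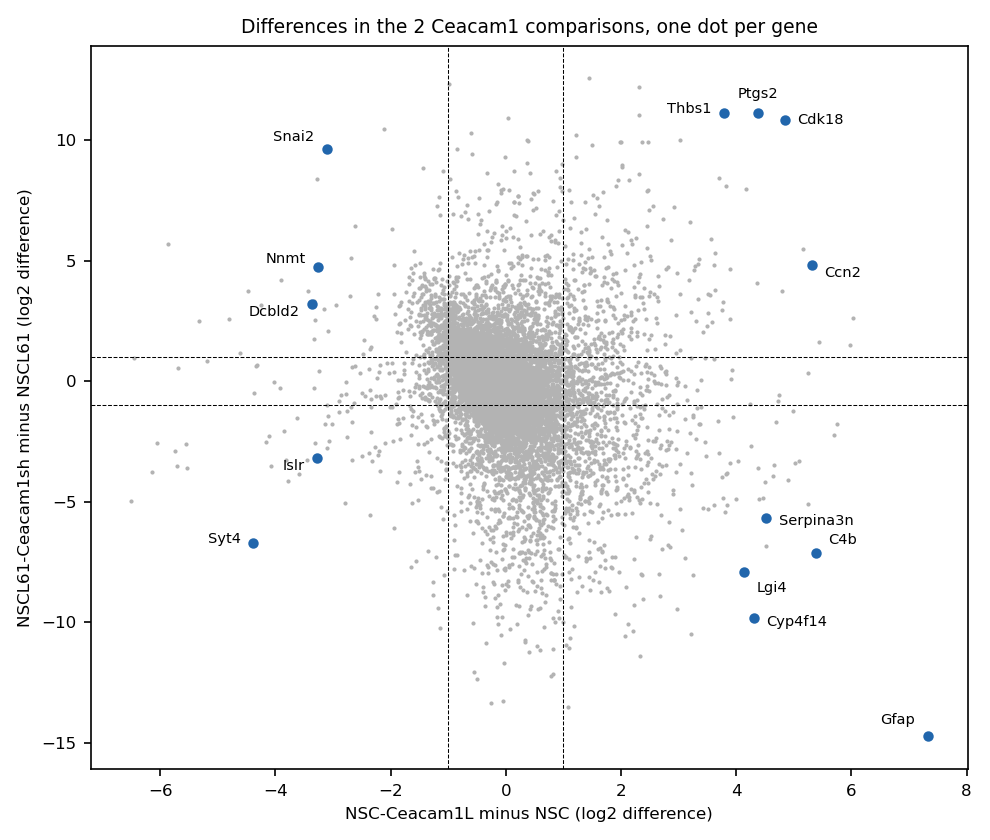
Log2 difference of each gene in the 2 Ceacam1 comparisons (dots, genes well above background on at least 1 array of each comparison, dim signals drawn as measured), with named genes in blue and dashed lines at 2-fold. In the lower right, Gfap (7.33 for NSC-Ceacam1L minus NSC), C4b and Lgi4 were higher with Ceacam1L and lower with the hairpin.

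Of 14301 genes evaluated in both comparisons, 569 were higher with Ceacam1L and lower with the hairpin, against 279 for independent lists of those sizes and a mean of 354 when differences were permuted among genes of like signal (central 95% from 326 to 382). In the reverse direction 362 genes were lower and then higher, against 146 for independent lists and a permuted range of 126 to 166. Genes higher in both numbered 330 (248 for independent lists, permuted range 229 to 279), and genes lower in both 137 (164, permuted range 161 to 204). Of the 1398 genes that differed in both, 66.6% went in opposite directions, and across genes, which are not independent replicates, the differences had a Pearson correlation of -0.19 and a Spearman correlation of -0.31. The 2 comparisons share no array. The counts lower with Ceacam1L and higher with the hairpin, and lower in both, were 205 and 91 under cyclic loess and 129 and 67 under spike-in scaling, and that of genes higher in both was 566 under spike-in scaling. With normexp background correction the 4 counts, in the order given above, were 315, 208, 136 and 54. With signals required well above background on both arrays they were 241, 313, 138 and 61, so the first opposite count was the smaller there, as it was at 1.5-fold (1154 and 1322). In a check chosen after seeing the data, both opposite counts lay above their permuted range under every alternative, with ranges of 117 to 156 and 57 to 86 under normexp and of 101 to 138 and 91 to 127 with both arrays required. The count of genes higher in both lay inside its range in these 2 settings, under median and spike-in scaling, without a filter on dim probes and at 1.5-fold, and the count lower in both lay inside its range under spike-in scaling and at 3-fold.

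NSCL61 was set against NSC to describe the backgrounds in which the manipulations were made. Gfap was 2017-fold higher on the array labelled NSCL61 (10.98 ± 0.25), and other large positive differences were those of the collagen VI genes Col6a1 (9.85 ± 0.28) and Col6a2 (7.72), the calcium binding protein S100a4 (9.15) and calponin Cnn1 (7.62). The homeobox gene Hoxa7 was at least 266-fold higher. Slc16a3 (-8.54), the phospholipase Pla2g7 (-8.30), the ketone enzyme Bdh1 (-6.39), Bmp7 (-6.14) and the MHC class II gene H2-Ab1 (-6.01) were lower. Mitotic genes were lower too.

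Of 29 STAT3 list genes, 17 were higher and 4 lower (median 1.77), including the interleukin-6 receptor Il6ra (4.55), Socs3 (4.30) and Cebpd (3.83). Fibroblast genes (12 higher and 5 lower of 21) had a median of 1.92, or 0.49, inside the random range, with genes seen on 1 array at their bound, the mesenchymal factor Twist2 being at least 29.5-fold higher and Fbln2 differing by -6.11. Astrocyte genes (12 higher and 4 lower of 25, median 0.80) included Agt (3.91) and Gja1 (3.53), and neuron genes (10 and 3 of 25, median 0.75) included Tubb3 (4.23). Of 24 BMP and TGF-beta genes, 10 were higher and 2 lower (median 0.67), among them Tgfbi (4.17). Chemokine (0.88, or -0.37 without a filter on dim probes), NF-kB (0.59) and EGFR, PDGF and FGF gene medians (0.34) were also above the random range.

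In the G1/S list 25 of 28 genes were lower and 0 higher (median -2.05), including Tk1 (-4.87) and Ccne1 (-3.13), and in the mitotic list all 31 of 31 were lower (median -2.07), including Ccnb2 (-4.04) and Plk1 (-2.36). Ras-MAPK genes (6 higher and 16 lower of 31, median -1.05, or -0.57 with normexp background correction) included the feedback genes Spry4 (-3.29) and Dusp6 (-2.93). Antigen presentation genes had a median of -0.95 (1 higher and 7 lower of 16), and cholesterol genes one of -0.89 (0 higher and 10 lower of 22), including Dhcr7 (-2.65). Hypoxia (-0.49), Wnt (-0.46), neural stem (-0.32) and ribosomal protein genes (-0.29) were also below the random range.

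The medians of Notch (0.25), microglia (0.43), endothelial (0.53), Hedgehog (-0.21) and housekeeping genes (-0.19) lay inside it. So did those of Src (0.15), interferon (0.14), cadherin (0.20), matrix (0.10) and unfolded protein response genes (0.16), which turned negative under spike-in scaling, and those of oligodendrocyte (-0.03) and p53 target genes (0.00), of which the first changed sign under cyclic loess and the other under median scaling, quantile normalization and spike-in scaling. In the unfolded protein response list the stress genes Trib3 (4.41), Atf3 (4.17) and Ddit3 (3.52) were higher. In all, 2178 of 15236 genes (14.3%) were higher and 2135 (14.0%) lower on the array labelled NSCL61 than on NSC, of which 791 and 701 were well above background on 1 array only. With normexp background correction the counts were 1367 and 1390. The share of calls that were higher was 50.5%, and 39.2% under spike-in scaling.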

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

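All tests in this part were chosen after the result they address was seen.

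If both manipulations acted through Ceacam1 alone, opposite differences would be looked for in the 2 Ceacam1 comparisons, and 5 gene lists lay outside the random range in the same direction in both, while 8 did so in opposite directions. The difference between the comparisons was not tested. Fibroblast genes had medians of 0.56 for NSC-Ceacam1L minus NSC and 1.92 for NSCL61-Ceacam1sh minus NSCL61. Extracellular matrix genes had medians of 0.23 and 1.53. Interferon genes had medians of 1.37 and 1.01. Chemokines and cytokines had medians of 0.60 and 4.39, the former with 1 gene higher and 2 lower of 11 and at -0.43 without a filter on dim probes. Hypoxia genes had medians of -1.68 and -0.40, the latter positive under median and spike-in scaling. Among probes without a gene name, which entered no comparison of genes, 1453 were well above background on NSC-Ceacam1L and not on NSC (689 the reverse), and 1008 on NSCL61-Ceacam1sh and not on NSCL61 (2139 the reverse).

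The array labelled NSCL61-Ceacam1sh stood apart from the other 3, with glial genes lost and fibroblast and cytokine genes gained. Poor labelling or hybridisation of that array would shift the spike-in probes. Their largest difference from NSCL61 was 0.25 on the log2 scale before scaling. These unscaled signals cannot speak to the scaling or to the quality of the cells' RNA. Median and spike-in scaling moved the median of all genes from 0.02 to 0.43 and 0.45, far less than the astrocyte median of -5.85. Other cells mixed with NSCL61 would leave the astrocyte genes at the share of NSCL61 cells that remained, if those cells kept their astrocyte signal. A median of 1.73% of the NSCL61 signal was kept over 25 genes. A much larger share of cells with the astrocyte signal of NSCL61 would not give these values. Cells that had lost this signal under the hairpin could make up any share, so for them the values set no limit. A mixture with such cells and a culture made up almost wholly of other cells stay open. RNA of a non-neural cell type in place of the labelled cells stays open: of 16 forebrain transcription factors seen on NSCL61, 12 were well above background on NSCL61-Ceacam1sh too, but only 5 within 2-fold, with 4 lower and 3 higher, and the median difference of the 16 was -1.37. Cells of another origin or a wrong label remain open, since Xist on that array lay at -4.47 relative to the lowest of the other 3 arrays, which spanned 1.43. The loss of an X chromosome or of Xist in culture would give the same value. The other genes of the sex-linked list, all Y-linked, were not well above background on any array. On both NSCL61 arrays only, 141 genes were well above background, 3 of them above the 75th percentile of both. These counts were 135 and 0 on NSCL61-Ceacam1sh and NSC-Ceacam1L only, and 31 and 0 on NSCL61-Ceacam1sh and NSC only. They were 223 and 0 on NSC-Ceacam1L and NSCL61 only, and 248 and 11 on the NSC arrays only. The count of 141 alone therefore does not mark a shared origin. An effect of the Ceacam1 hairpin may also account for the distance of that array and cannot be told apart from the explanations left open. The 1 probe that lists a Ceacam1 transcript differed by 0.66 and was not well above background on NSCL61.

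Cell cycle and Ras-MAPK genes were lower on the array labelled NSCL61, a line known to carry an activated Ras, than on NSC. Scaling of the arrays does not account for the mitotic genes, whose median closest to 0 over 5 other scalings or normalizations was -1.88, while for the Ras-MAPK genes processing stays open as part of the difference, since their median went from -1.05 to -0.57 with normexp background correction. Exchanged labels of the 2 NSCL61 arrays stay open: Hras differed from NSC by -0.31 on the array labelled NSCL61 and by 1.37 on the one labelled NSCL61-Ceacam1sh, but the Ras-MAPK list differed from NSC by a median of only 0.21 over 32 genes on the latter and was lower on the former. Whether the Hras probe reads an introduced Ras gene is not known. A biological difference between NSCL61 and NSC stays open and was not tested apart from this.

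Interferon genes were higher as a list on both Ceacam1-manipulated arrays, but the genes called higher in both numbered 9, against 7.68 for independent calls, which does not show a response shared gene by gene. A low level on the NSC array would bear on the comparison with NSC only, since the other uses no NSC array. For that comparison, the list would then be as high on NSCL61 minus NSC as on NSC-Ceacam1L minus NSC, where its median was 1.37. On NSCL61 minus NSC its median was 0.14, inside the random range of -0.37 to 0.45, so it was not as high there. The SD over 27 genes, 1.87, gives the spread of the genes and not the error of the median. NSCL61 is another line with 1 array, and its own interferon level cannot be set apart, so a low level on NSC stays open for that comparison. The labels give the same transfection and selection for all 4 groups but not what vector the parental cells carried, so an effect of the vector was not tested and cannot be told apart from one of Ceacam1.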

How the results depend on the processing

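Spike-in scaling was chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each group had 1 array, and for the same reason no array could be left out. Leaving out saturated probes removed nothing. Of 879 list medians under the alternatives, 835 kept their place relative to the random range, 27 moved inside it, 13 moved outside it and 4 outside it changed sign. A further 52 inside the range changed sign. Part of this was fixed in advance. Median and spike-in scaling shift all genes of a comparison alike, so a list and its random range moved together. The deposited values differed from the scanner signals by almost a constant. Of 88 list medians each, 87 were counted as keeping their place under median scaling, 87 under spike-in scaling, 88 with the deposited values and 88 without saturated probes. The exception under median and under spike-in scaling was the hypoxia list between the NSCL61 arrays, set apart for its change of sign. The counts of genes per comparison and of the overlap stayed within 1.5 times the reported ones except as follows, and the cause was not tested beyond what each alternative itself removes or adds.

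Under normexp background correction, 741 genes were higher and 523 lower on NSC-Ceacam1L than on NSC, and 1367 and 1390 on NSCL61 than on NSC. The overlap held 315 (higher with Ceacam1L, lower with the hairpin), 208 (the reverse), 136 (higher in both) and 54 (lower in both), and the Ceacam2 probe that also lists Ceacam1 differed by -0.0016 between the NSCL61 arrays, while it was past 2-fold under quantile normalization (1.12), median scaling (1.08), cyclic loess (1.01) and spike-in scaling (1.10). Requiring signals well above background on both arrays left 887 higher genes on NSC-Ceacam1L, 2351 lower on NSCL61-Ceacam1sh, 1387 higher on NSCL61, and overlaps of 241, 138 (higher in both) and 61 (lower in both). Without a filter on dim probes, 1473 genes were lower on NSC-Ceacam1L and 260 lower in both. At 1.5-fold the counts were 2609 and 2572 between the NSC arrays, 3549 and 3345 between NSCL61 and NSC, and 1154, 1322, 586 and 404 in the overlap. At 3-fold they were 917 and 368, 1341 and 1389, and 249, 57, 175 and 48, with 2350 higher on NSCL61-Ceacam1sh. Under cyclic loess 205 genes were lower with Ceacam1L and higher with the hairpin and 91 lower in both. Under spike-in scaling 2465 genes were higher and 465 lower on NSC-Ceacam1L, and the overlap held 129 (lower, then higher), 566 (higher in both) and 67 (lower in both).

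The median of all genes moved by scaling from -0.10 to 0.12 (cyclic loess) and 0.28 (spike-in) between the NSC arrays, from 0.02 to 0.43 (median scaling) and 0.45 (spike-in) between the NSCL61 arrays, and from 0.03 to -0.21 (spike-in) between NSCL61 and NSC. The share of calls that were higher moved from 63.3% to 76.3% and 84.1% (50.4% at 1.5-fold), from 49.3% to 64.6% and 65.0%, and from 50.5% to 39.2%. The hypoxia list between the NSCL61 arrays changed sign to 0.0249 (median scaling) and 0.0402 (spike-in), and the chemokine list without a filter to -0.43 between the NSC arrays and -0.37 between NSCL61 and NSC. Dim signals limit the rest: genes seen on 1 array only have a bound, not a value.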

Other observations

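The tests in this part were chosen after the values were seen, and the genes named here were chosen by the criteria given.

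Genes above the 75th percentile on 3 arrays and not well above background on the fourth were counted for each array. The array labelled NSCL61-Ceacam1sh lacked 155 such genes, among them Bcan, Olig1, Hes5 and Ptprz1, the array labelled NSCL61 lacked 17, NSC lacked 1 and NSC-Ceacam1L 0. On NSCL61 they included Churc1, at -6.90 against 2.33, 2.72 and 3.04 on NSC, NSC-Ceacam1L and NSCL61-Ceacam1sh. Genes above the 75th percentile on 1 array and not well above background on the other 3 numbered 66 on NSCL61-Ceacam1sh, among them Il1rl1, Mmp3 and Prl2c5, and 5 on NSCL61, among them the homeobox gene Hoxa3 at 1.04 and the lung surfactant gene Sftpc at 0.37.

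Genes seen in 1 pair of arrays only, above the 75th percentile on both and not well above background on the other 2, were also counted. Both NSC arrays shared 11 such genes of 8000, with 1.03 from independent losses, including the collagen Col26a1 (2.89 and 3.26 against -6.58 and -6.57), the carbonic anhydrase Car3 and the laminin Lama1. Both NSCL61 arrays shared 3 of 7206, among them the interferon-inducible Ifi204 and the mesenchymal factor Twist2, with 0.0104 from independent losses. Each of the other 4 pairs had 0. For the NSC pair and the NSCL61 pair, the remaining 2 arrays were labelled as 1 line, and the NSC arrays correlated at 0.973. Losses on them need not be independent, so an excess over the numbers given may come from the likeness of those 2 arrays.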
